A study of Mus musculus with 2 samples.

How the data were processed

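The sources used here were the labels of 2 mouse retina samples and the row and column names of their joint table. Libraries were made with version 3.1 of the 10x Genomics Chromium 3′ kit and processed with Cell Ranger 7.0.1 at default settings, per the labels' protocols. The submitters' processing notes also name the genome build mm10 and Seurat version 4, without a role. As background, this Cell Ranger release counts intronic as well as exonic reads unless told otherwise. The annotation release and the use of strand are not given in the sources used here. The authors deposited the names as part of a filtered table, so the barcodes are those the pipeline had called as cells. Calling depends on each library's distribution of molecules per droplet, which affects the number of barcodes kept. No value of expression was analysed here, so no filter on cells, doublet call, clustering, normalization or test of expression was run.

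Barcodes were assigned to samples by their suffix, which the labels tie to a sample: 1 for the control and 2 for the Rbpj deletion. There were 0 barcodes with another suffix. The labels name no animals, and each group is 1 library, so no test between groups and no p-value was computed. Counts of barcodes are given with exact Poisson 95% intervals, and shares and the ratio of the 2 counts with intervals from the exact binomial (Clopper-Pearson). All of these cover counting error only.

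The number of barcodes found in both libraries was compared with the number expected for independent draws from a common pool, and with the hypergeometric 95% range. The plan, fixed before the data were examined, took the expected number from independent draws from the set of barcodes seen. The pool used here also holds barcodes that were not seen. How to build this pool was chosen after the lists and their overlap had been seen. The first 8 and the last 8 bases of a barcode were counted as separate blocks. The pool was every combination of a first and a last block seen in either library whose adjoining bases, at positions 8 and 9 from the 5′ end, formed a pair that occurs in the lists. This gave 3687360 barcodes. It is an upper limit for blocks that have been seen, since not every combination need exist in the kit. Pools of 3500000, the size generally given for this kit version, and of 6800000 barcodes were added after the lists had been seen, both as background from outside the sources used here. The calculation was tested on simulated lists of the real sizes. In lists drawn from 3500000 barcodes, the interval of observed over expected held 1 in 19 of 20 simulations without added shared barcodes. It excluded 1 in all 20 simulations with 200 added, with a mean excess of 206. In 100 simulations from a pool built of blocks, the lowest estimate was 100% of the true pool, and the interval held 1 in 95. The simulated pool held every allowed combination of its blocks, so these simulations cannot test whether that holds in the kit. The ratio of 2 used as a limit below was not simulated.

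Gene identifiers were matched to GENCODE release M21, an annotation of GRCm38, which is the same assembly as mm10. Of the 32285 identifiers, 32235 (99.8%) matched and 50 did not. Of the matched identifiers, 31502 had the same symbol in both and 733 had another. The symbols of 38 genes were each used by more than 1 identifier, which involved 78 identifiers and none of the genes named in the lists. All coordinates are from this annotation and count from 1. Of the matched genes, 21702 are protein coding, 5605 are lincRNAs and 2955 are antisense genes. Overlaps were sought among the matched genes only, by span and by the exons of all transcripts. They describe the annotation and not the authors' counts.

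The rule for named genes, fixed before the data were examined, takes the genes with the most extreme ratios in Müller glia and all members of 6 fixed lists. Where no expression values are used, it provides only for looking up the list members in the gene list. The rule's genes and the 14 lists of cell type markers were looked up by symbol. Genes described beyond their presence were those of the Rbpj family and those with the overlaps described. These were chosen after the annotation had been seen. The planned analyses of the Rbpj level, cell class shares, gene lists and most changed genes in Müller glia-like cells were not run. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.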

Results

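The data collected were single-cell RNA sequencing libraries of dissociated mouse retina, made with a droplet method that reads the 3′ ends of polyadenylated RNA. There were 2 libraries, 1 per group, so no difference between the groups has a replicate check. The control library carried a nuclear-envelope GFP reporter (Sun1-GFP) and is labelled with Glast, the name of the glutamate transporter gene Slc1a3 that is active in Müller glia, the main glial cell of the retina. The other library carried the same labels together with a deletion of Rbpj, the DNA-binding protein through which activated Notch receptors switch on their target genes. The genotypes are labelled wild type control and Rbpj deletion, and these labels do not say in which cells Rbpj was deleted. The title of the series names the question: whether blocking Notch signalling and the NFI transcription factors turns glia of the adult retina into neurons. Only the control and Rbpj deletion libraries were analysed here. The material used held the cell barcodes and the gene list of their joint count table, and not the counts. Gene expression, cell classes and the level of Rbpj in either library were therefore not analysed here, and the number of reads or molecules per cell is unknown.

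The control library gave 28902 cell barcodes and the Rbpj deletion library gave 38210. With exact Poisson 95% intervals, these counts span 28570 to 29237 and 37828 to 38595, and the intervals cover counting error only. The Rbpj deletion library thus held 1.32 times as many called cells as the control (exact 95% interval 1.30 to 1.34), a difference of 9308 barcodes. It made up 56.9% of the 67112 barcodes (Clopper-Pearson 95% interval 56.6% to 57.3%). With 1 library per group this compares 2 libraries and not the genotypes, and how many cells were loaded is not given in the sources used here. No barcode was repeated within a library, and 290 of the 16-base barcodes occurred in both. These made up 1.003% of the control barcodes and 0.759% of the Rbpj deletion barcodes.

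The gene list of the joint table held 32285 genes, each with its own Ensembl mouse identifier. Rbpj (ENSMUSG00000039191) was among them. On GRCm38, the assembly also called mm10, Rbpj spans chromosome 5 from 53466152 to 53657362 on the plus strand and has 12 annotated transcripts. The most distal last exon, shared by 3 of these transcripts, lies from 53653305 to 53657362. Its stop codon is at 53653618 to 53653620, which leaves a 3′ UTR of 3742 bases, from 53653621 to 53657362. A 3′ library reads mainly the 3′ ends of transcripts, and the other annotated transcripts of Rbpj end at other positions. Some of these positions may lie close by, since annotated exons from 53653305 to 53657358 and from 53653305 to 53656137 end within that last exon. Where intronic reads are counted, reads can also fall elsewhere in the span. Which exons the deletion removes is not given in the sources used here. If the deleted part lies outside the most distal last exon, reads from that exon do not show directly whether that part was removed. Rbpjl (ENSMUSG00000017007), a related gene on chromosome 2 from 164403141 to 164415448, was also listed. The annotation places 2 processed pseudogenes of Rbpj elsewhere: Rbpj-ps1 on chromosome 4 from 49350522 to 49351527 and Rbpj-ps3 on chromosome 6 from 46529354 to 46530794. Neither of the pseudogene identifiers was among the 32285 genes. Only 1 of the genes matched to the annotation is a processed pseudogene, so this absence is not particular to Rbpj. Inside the Rbpj span, Gm10441 and Gm40304 were listed on the minus strand, and neither shares an exon with Rbpj.

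**Figure D1:**
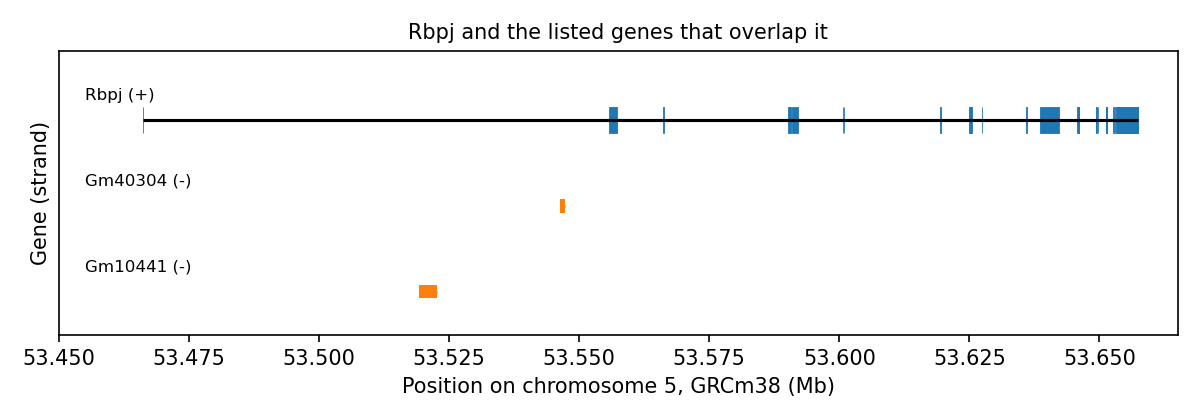
Map of Rbpj on chromosome 5 (x axis, position in Mb on GRCm38), with 1 row per gene and its strand in brackets. The black line is the span of Rbpj, blue boxes are the exons of all its annotated transcripts, and orange bars are the spans of Gm10441 and Gm40304, which overlap Rbpj on the opposite strand between its exons.

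The genes through which the comparison of control and Rbpj deletion would be read were all present in the gene list. All 17 members of a Notch pathway list were found. It includes the receptors Notch1, Notch2 and Notch3, the ligands Dll1, Dll4 and Jag1, and the target repressors Hes1 and Hes5. All 4 NFI factors were found as well: Nfia on chromosome 4 from 97772734 to 98118874, Nfib on chromosome 4 from 82290173 to 82705750, Nfic on chromosome 10 from 81396186 to 81455635 and Nfix on chromosome 8 from 84699876 to 84800344. The same held for 12 Müller glia identity genes, among them Glul (glutamine synthetase) and Rlbp1 (the retinaldehyde-binding protein). It also held for 7 gliosis genes such as Gfap, 14 neurogenic genes such as Neurog2, and 8 cell cycle genes such as Mki67. The 14 marker lists of retinal and other cell types were complete too, from Müller glia, rods, cones, bipolar, amacrine, horizontal and ganglion cells to neurogenic progenitors, astrocytes, microglia, endothelial cells, pericytes, pigment epithelium and red blood cells. Together the 20 lists named 125 genes, of which 17 stood in more than 1 list. All 7 neurogenic progenitor markers and all 8 Müller glia markers were also members of another list. Presence in the gene list says nothing of expression.

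Several of these genes share their position with another listed gene. An overlap on the same strand bears on how reads there could be assigned. An overlap on the opposite strand does so only where counting ignores strand. The use of strand is not given in the sources used here. Of the 125 genes, 82 overlapped no other listed gene and 43 overlapped at least 1. On the same strand, 6 overlapped another gene, and for 2 of them exons overlapped. The first was Neurod1, a neurogenic transcription factor on chromosome 2 from 79452521 to 79456751, which lies wholly within Cerkl (79330543 to 79456785). The second was Nr2e3, a rod transcription factor on chromosome 9, which shares exonic sequence with the non-coding RNA gene Gm15507. Sox2, a progenitor and Müller glia transcription factor on chromosome 3 from 34650405 to 34652461, lies between exons of the longer non-coding gene Sox2ot (34104270 to 34682619). Cx3cr1, Nfib and Rbpms contain or overlap same-strand genes without sharing exons with them. On the opposite strand, 41 of the 125 genes overlapped another gene, and 29 did so within exons. These 29 include Nfia, Nfic, Nfix, Notch1, Notch3, Hes5, Glul and Otx2. The neurofilament genes Nefl and Nefm, both ganglion cell markers, overlap each other in this way on chromosome 14. Hes1, Notch2, Neurog2, Rlbp1, Sox9 and Gfap overlapped no other listed gene.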

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

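The way the pool was estimated from the lists, and the pools of 3500000 and 6800000 barcodes, were chosen after the lists had been examined. Leaving out the 290 barcodes found in both libraries gave 28612 for the control and 37920 for the Rbpj deletion, both within the intervals of the full counts, and a ratio of 1.33. Those intervals cover counting error only, and removing 290 barcodes is too small a change to leave them. This is therefore no test of the counts. The comparison of shared barcodes with chance depended on the assumed pool. Observed over expected was 0.97 for the 3687360 barcodes that the lists allow, 0.92 for 3500000, 0.097 for 368736, 1.79 for 6800000 and 1128 if every 16-base sequence were possible. The change follows from the construction, since the expected number is inversely proportional to the pool. The alternatives planned for expression (cell filters, doublets, cluster resolution, scaling and thinning) were not run, because no expression values were analysed here. No paired analysis was possible because each group has 1 library. Depth per cell is unknown, so what depth limits cannot be stated.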

Other observations

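The comparison of shared barcodes with chance was planned, but the way the pool was estimated, the pools of 3500000 and 6800000 barcodes and the test below were chosen after the lists had been seen. The barcodes of both libraries had a block structure. Their first 8 bases took 3839 forms and their last 8 bases 3842 forms, of 65536 possible for each. The base at position 9 was fixed by the base at position 8: 4 of 16 base pairs occurred there, in both libraries. Of the 120 pairs of positions, this was the only one at which any base pair was missing. Every first block was seen at least 4 times over the 66822 distinct barcodes, as were all but 2 of the last blocks. Together the blocks allow 3687360 barcodes.

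The control and Rbpj deletion libraries had 290 barcodes in common. One hypothesis is that reads or droplets passing between the libraries may be the source of most of them, which needs at least 2 times the number expected by chance. With the pool that the blocks allow, 299 were expected (95% range 266 to 334), and observed over expected was 0.97 (95% interval 0.86 to 1.09). With this pool, the ratio argues against passage as the source of most of the shared barcodes called as cells. The limit of 2 was set after the overlap was known. Passage that left too few molecules for a barcode to be called cannot be seen in these lists. A smaller true pool would lower the ratio. A pool of 6800000 barcodes, which exceeds what the blocks seen allow, gave 1.79 (95% interval 1.59 to 2.003). That interval reaches 2, so with that pool the question would not be decided. Passage in a small number of barcodes, within the interval, stays open, and no biological explanation was tested.

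Both libraries held more called cells than the 10000 per channel that is the usual upper target of this kit, as background: 2.89 times as many in the control and 3.82 times as many in the Rbpj deletion. How many channels stand behind each suffix is not given in the sources used here. Doublets were not called here.

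Among the 2251976716 pairs of barcodes within and between the libraries, 0 pairs differed at exactly 1 base. If every 16-base sequence were possible, 25.2 such pairs were expected. Among the blocks themselves, 0 pairs of first blocks and 3 pairs of last blocks differed at exactly 1 base while sharing the adjoining base. Barcodes made of these blocks can differ at exactly 1 base only through those 3 pairs. The 0 therefore follows largely from the blocks and says little about the libraries. At each of the 16 positions the share of each base lay between 22.8% and 28.4% and differed between the libraries by at most 0.94 percentage points. The shares at positions 8 and 9 are the same values under exchanged bases, as the tie between these positions requires.

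All 32285 listed genes carried Ensembl mouse identifiers, and 0 had any other kind of identifier. A transgene such as the GFP reporter, where a custom reference adds it, would normally carry an identifier of another kind.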
